A study of Homo sapiens with 6 samples.

How the data were processed

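Small RNA libraries of 6 samples were analysed, 3 from vesicles of control MHCC97H cells and 3 from vesicles of cells given xanthatin at 4 µmol/L for 24 h. Per the labels' protocols, DMSO was at 0.5%, the medium held 5% fetal bovine serum and 5% serum depleted of exosomes, vesicles were pelleted for 70 min at 120000xg, and RNA of 18 to 30 nt was selected on a gel.

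Per the file headers, the authors deposited for each sample a count per mature miRNA name and a TPM value. The deposited counts were whole numbers that were not normalised. The deposited TPM equalled the count divided by 1 constant per library, with no length term, and it was scaled to a total larger than the miRNA counts. What the authors counted in that total is not stated. The total, computed from the values, was 12130988, 9917946 and 9408297 in control and 28875359, 31859012 and 26867789 in xanthatin libraries. The genome build was hg38 per the submitters' processing notes, while the aligner, miRNA database, counter and predictor of new sequences are not given in the sources used here. No row had 0 counts in all libraries, and 45 rows named several miRNAs.

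Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test on group, with TMM scaling and the default count filter of edgeR (minimum count 10), which left 254 miRNAs (178 known, 76 predicted). p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The SE is the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes. Where a group had 0 counts, the fold is a bound against 3 counts over the group, equal to 12.5 CPM in control and 4.75 CPM in xanthatin libraries. With a library left out, the 3 counts were taken over the libraries left in that group. Where a group had 1 to 3 counts, the ratio of the groups' count rates is given with its exact 95% Poisson interval, which covers counting error only. For a single library, 3 counts equal 34.7 to 39.9 CPM in control and 12.5 to 16.7 CPM in xanthatin libraries. Such floors cover counting error only, since the reads carry no molecular identifiers.

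Before the data were examined, 21 lists of miRNAs were fixed, matched by name with the arm removed, and 19 with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01. The lists share members, such as miR-122, miR-192, miR-143 and miR-10b. The named miRNAs were also chosen by a rule fixed then: the 12 highest and 12 lowest called miRNAs by log2 fold change whose groups did not overlap and whose mean CPM in the higher group was at least 10, the 10 most abundant, and the 2 most abundant members of each list (4 for a list that passed). Members named beyond this rule (let-7e-5p, let-7d-3p, miR-203a-3p, miR-21-5p, miR-183-5p, miR-182-5p, miR-92a-1-5p, miR-106b-3p, miR-99b-3p and miR-320c) were chosen after their values were seen. miR-194-5p, miR-205-5p, miR-126-3p and miR-371a-3p were also named outside this rule, as were those said below to be chosen after their values were seen. Measures of library composition were compared with a two-sided exact permutation test.

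On simulated counts for the same 1007 miRNAs, with 200 changed in each of 10 draws, the test recovered 5.18% of tested 2-fold, 28.2% of 4-fold and 49.1% of 8-fold changes, and 2.22% of calls were false. For the list test, the let-7 list was changed by design in simulated counts. It was called in 10 of 10 draws, and 0 of 179 tests of lists not overlapping it were called. The 10 of 10 is recovery of a planted change, so it is no evidence for the let-7 result of the real libraries. The simulated counts were drawn independently for each miRNA, so list members were not correlated, and these draws do not settle the choice of correlation. With an estimated correlation, 0 lists were called in the real libraries.

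Precursor positions come from GENCODE release 29 (GRCh38), where 482 of the 497 known names matched a miRNA gene. A mature name can come from several precursors, which the deposited counts do not separate.

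Alternatives were other scalings (RLE, upper quartile, totals only, totals without the 10 most abundant), no filter or a mean CPM of at least 10, DESeq2 1.42.0, limma-voom, limma-trend on CPM with pseudocounts of 0.1, 1 and 10 and on the deposited TPM plus 1, a robust fit, a replicate block, leaving out each library, known names only, a 2-fold threshold, camera with an estimated correlation and fry. Thinned libraries, the total implied by the TPM as library size, and leaving out novel550_mature were added after the data were seen. No replicate pair held identical counts, and the chi-square per degree of freedom between replicates was 16.1 to 21.3.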

Results

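Small RNA of 18 to 30 nt was sequenced from extracellular vesicles (exosomes) released into the culture medium by MHCC97H, a human hepatoma cell line of high metastatic potential. The 6 samples were 3 controls and 3 from cells exposed to xanthatin, a sesquiterpene lactone of Xanthium plants, at 4 µmol/L for 24 h. The table of counts held 1007 miRNA names, of which 497 were known human miRNAs and 510 were sequences predicted by the authors. The control libraries held 80088, 70228 and 63965 miRNA counts, and the xanthatin libraries held 238442, 267956 and 204520, so depth differed between the groups. The comparison asked which miRNAs of the vesicles differ after xanthatin.

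Relative to the scaled miRNA counts, vesicle libraries of xanthatin-treated cells held far less miR-122-5p, the main miRNA of hepatocytes. They held more of the let-7 family, whose members repress growth-promoting transcripts. Whether the miR-122-5p reads came from the cells or from serum in the medium stays open. miR-122-5p fell from 48383 ± 9796 normalised counts (CPM; SD, n = 3) in control to 1086 ± 116 in xanthatin libraries, a log2 fold change of -5.48 (SE 0.21, adjusted p = 1.98e-05). let-7f-5p rose from 5010 ± 406 to 29996 ± 835 CPM, a log2 fold change of 2.58 (SE 0.10, adjusted p = 1.98e-05). Of 14 listed miRNA names of the chromosome 14q32 cluster, the 4 that were tested fell, to 3 counts or fewer in every xanthatin library. In all, 77 of 254 tested miRNAs passed the edgeR quasi-likelihood test at an adjusted p under 0.05, with 34 higher (22 without xanthatin replicate 1 or 3) and 43 lower in xanthatin libraries.

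**Figure D1:**
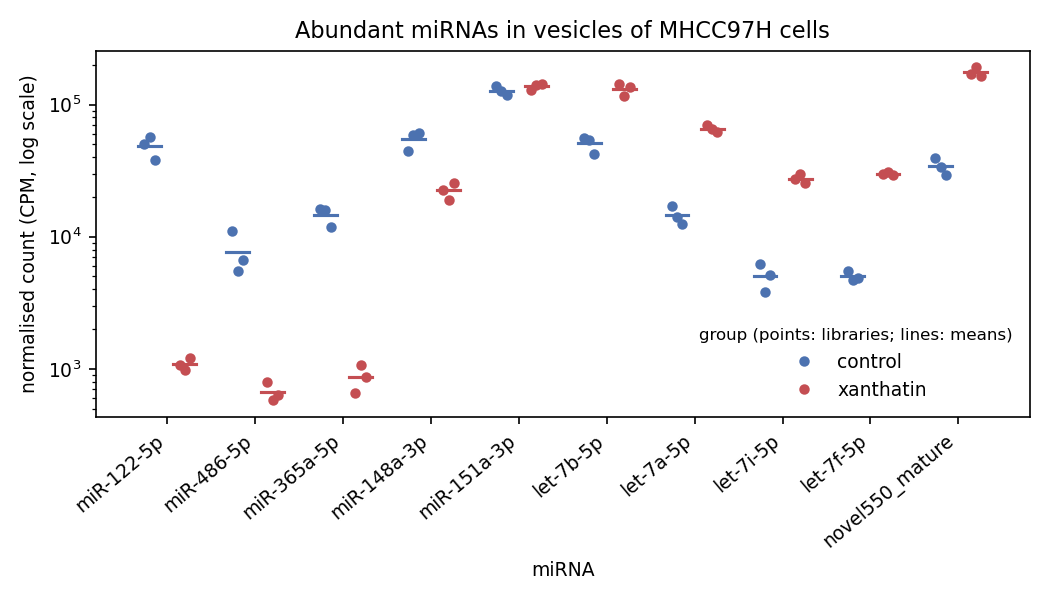
Normalised counts (CPM) on a log scale for 10 abundant or strongly changed miRNAs, with a point for each of the 3 control and 3 xanthatin libraries and a line at each group mean. miR-122-5p, miR-486-5p, miR-365a-5p and miR-148a-3p lie lower in the xanthatin libraries, the 4 let-7 members and novel550_mature lie higher, and miR-151a-3p overlaps between the groups.

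Of the 10 tested members of the let-7 family, 8 rose (9 adjusted over the list alone) and the others, let-7e-5p and let-7d-3p, had log2 fold changes of 0.75 and 0.45 (let-7e-5p passed with DESeq2 at 0.91, adjusted p = 0.0331). let-7b-5p rose from 51004 ± 7438 to 132117 ± 14142 CPM and let-7a-5p from 14566 ± 2375 to 65742 ± 3806 CPM, log2 fold changes of 1.37 (SE 0.14) and 2.17 (SE 0.14). let-7i-5p rose by a log2 fold change of 2.44 (SE 0.20), and miR-98-5p by 2.77 (SE 0.75, adjusted p = 0.035). The family took 9.84% ± 0.88 of the counts in control and 26.0% ± 0.86 in xanthatin libraries. The camera set test gave an adjusted p = 2.77e-08 with the preset correlation and adjusted p = 0.0789 with an estimated correlation. Members of this family differ by few bases, so reads may have been shared between them in the deposited counts. The call of miR-98-5p, whose control libraries held 3, 11 and 2 counts, was lost without control replicate 1 or 3 or any xanthatin replicate (adjusted p = 0.0739 to 0.0977), and without control replicate 2 its log2 fold change was 3.96 (adjusted p = 0.0133). That call was also lost with upper-quartile factors (adjusted p = 0.0522) and a filter of mean CPM 10 (0.0808).

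Of 14 miRNA names on the list of the 14q32 cluster, 4 had enough counts to be tested. All 4 fell, and all 4 did so adjusted over the list alone. With 3 counts or fewer in each xanthatin library, they passed the count filter through the control libraries. The list took 0.329% ± 0.092 of control counts. Its share was 0.0168%, 0.0019% and 0.0015% in xanthatin replicates 1, 2 and 3. In replicate 1 the tested members held 1 count, so untested members gave most of that share. miR-432-5p (549 ± 201 CPM) and miR-493-5p (227 ± 120 CPM) were read in every control library and had 0 counts in all xanthatin libraries, which makes them at least 116-fold and at least 47.8-fold lower against a floor of 3 counts over the group. miR-127-3p fell from 782 ± 392 to 4.16 ± 7.20 CPM, a ratio of 162 (exact 95% Poisson interval 54.5 to 792) on 3 counts in xanthatin libraries. All 3 were in replicate 2, without which it was at least 101-fold lower. miR-409-3p fell from 384 ± 102 to 1.58 ± 2.73 CPM, a ratio of 241 (42.3 to 9641) on 1 count in xanthatin replicate 1, without which it was at least 53-fold lower. In the GRCh38 annotation their precursors lie on chromosome 14 between positions 100869060 and 101065378, in introns of noncoding transcripts. miR-412-5p, the other of the 4 most abundant members, had too few counts for the test, with 53, 35 and 0 counts in control and 0, 1 and 0 in xanthatin libraries. The median log2 fold change was -7.68 as fitted and -7.02 with the members at 0 placed at their bound. The camera adjusted p was 0.00688, but 0.243 with an estimated correlation, 0.0565 with limma-voom and 0.0941 with libraries thinned to equal miRNA totals, where miR-493-5p had too few counts for the test.

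Of 8 tested hepatocyte-enriched miRNAs, 3 fell, 1 rose and 4 did not pass; adjusted over the list alone, 5 fell and 1 rose. miR-148a-3p fell from 54885 ± 9120 to 22469 ± 3297 CPM (log2 fold change -1.29, SE 0.17) and miR-483-5p, from an intron of the growth factor gene IGF2, from 6360 ± 862 to 2405 ± 530 CPM (log2 fold change -1.40, SE 0.22). Their raw counts were similar in the groups: 3837, 4684 and 4589 against 4776, 4595 and 4626 for miR-148a-3p, and 468, 519 and 534 against 526, 442 and 520 for miR-483-5p. miR-192-5p moved the other way, from 3978 ± 1677 to 9282 ± 499 CPM (log2 fold change 1.22, SE 0.34). The MIR122 precursor lies on chromosome 18 from 58451074 to 58451158, in an exon of the noncoding transcript MIR122HG. The list's camera adjusted p was 0.0380, and adjusted p = 0.542 with an estimated correlation. That call was lost without control replicate 1 (adjusted p = 0.0657), 2 (0.138) or 3 (0.119) and without xanthatin replicate 1 (0.279) or 2 (0.135). It was also lost with upper-quartile factors (adjusted p = 0.0788), known names only (0.0690), thinned libraries (0.110), the removal of novel550_mature (0.0506), limma-voom (0.227) and limma-trend (0.181 to 0.281). The call of miR-192-5p was lost without control replicate 1 or any xanthatin replicate (adjusted p = 0.0823 to 0.0943), with upper-quartile factors (0.0556) and with library totals only (0.0791). miR-194-3p, at -1.80 (adjusted p = 0.0585), passed without xanthatin replicate 3 (-2.47, adjusted p = 0.0201). It also passed with RLE, upper-quartile factors, totals only, the total implied by the TPM, DESeq2, limma-voom, each limma-trend fit and thinned libraries (-1.68 to -2.14, adjusted p = 0.0126 to 0.0497). The other arm, miR-194-5p, lay in the opposite direction, at 1.67, and did not pass.

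Of 6 tested miRNAs reported as enriched in extracellular vesicles, 3 fell and 1 rose, with the same counts adjusted over the list alone. miR-486-5p, abundant in red blood cells, fell from 7685 ± 2914 to 669 ± 110 CPM (log2 fold change -3.52, SE 0.33), miR-203a-3p fell by -2.27 (SE 0.54) and miR-122-5p fell as above. miR-203a-3p had 215, 67 and 60 counts in control and 55, 68 and 56 in xanthatin libraries. It was at -1.57 without control replicate 1 (adjusted p = 0.0310), and its call was lost without any one xanthatin replicate (adjusted p = 0.0717 to 0.0809). miR-146a-5p, induced by inflammatory signals, rose from 1109 ± 246 to 2695 ± 296 CPM. The list's camera adjusted p was 0.00981, adjusted p = 0.382 with an estimated correlation, and 0.0769 without xanthatin replicate 1. With limma-voom it was 0.183 and with limma-trend 0.160 to 0.184.

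Neither list of markers of cell types outside the culture passed the camera test. Blood and serum markers held 0.940% ± 0.290 of control counts and 0.136% ± 0.029 of xanthatin counts, with miR-486-5p (949, 432 and 497 counts in control, 167, 139 and 115 in xanthatin libraries) the member that fell among 4 tested (1 adjusted over the list alone; camera adjusted p = 0.422). Stromal and endothelial markers held 0.543% ± 0.116 and 0.0882% ± 0.015, and miR-143-3p and miR-10b-5p, 2 of 4 tested members (3 adjusted over the list alone), fell by log2 fold changes of -4.26 (SE 0.54) and -1.81 (SE 0.25). The camera adjusted p of the stromal list was 0.194, but 0.0133 without control replicate 2, 0.00235 with no count filter and 0.0135 with a filter of mean CPM 10; fry, which does not compare a list with other miRNAs, gave adjusted p = 0.0107 for it and adjusted p = 0.0183 for the blood and serum list. Names that overlap fragments of other RNA classes, a sign of RNA quality, held 0.645% ± 0.145 and 0.182% ± 0.052, and miR-1275 was the 1 of 4 tested members that fell (-2.25, SE 0.37; 1 adjusted over the list alone). Its list had a median log2 fold change of 0.21, a mean of -0.12 and a downward test direction (camera adjusted p = 0.853).

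**Figure D2:**
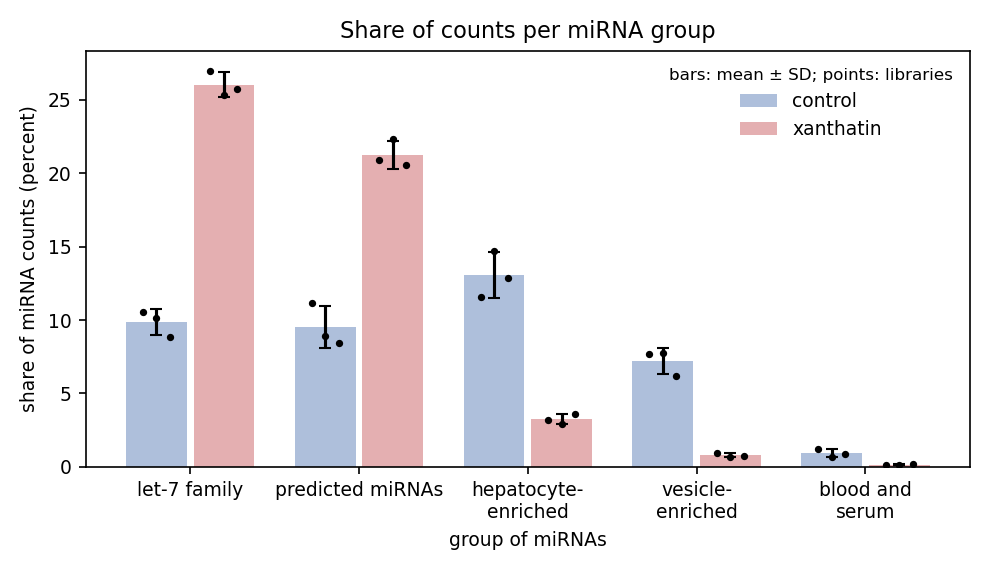
Share of miRNA counts, in percent, taken by 5 groups of miRNAs, with bars at the mean, error bars at 1 SD and points for the 3 control and 3 xanthatin libraries. The let-7 family goes from 9.84% to 26.0% and predicted miRNAs from 9.52% to 21.3%. Of the predicted miRNAs, novel550_mature alone takes 15.6% of xanthatin counts. The hepatocyte-enriched, vesicle-enriched and blood and serum groups lie lower in the xanthatin libraries. These groups share members. miR-122-5p (48383 CPM in control) is in the hepatocyte and vesicle groups, and miR-486-5p (7685 CPM in control) is in the vesicle and blood groups.

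Among the largest falls, miR-6892-5p (645 ± 260 CPM in control), novel135_mature (522 ± 229 CPM), miR-4658 (440 ± 203 CPM) and novel108_mature (389 ± 121 CPM) had 0 counts in all xanthatin libraries, at least 136-fold, 109.8-fold, 92.7-fold and 82.0-fold lower. miR-6529-5p fell from 5199 ± 525 to 50.3 ± 63.1 CPM (log2 fold change -6.66; -8.41 without xanthatin replicate 1). miR-365a-5p fell from 14646 ± 2428 to 863 ± 206 CPM (log2 fold change -4.08, SE 0.25), and miR-193b-5p, in the same noncoding host transcript MIR193BHG on chromosome 16, from 4994 ± 743 to 430 ± 206 CPM (-3.53, SE 0.41).

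Predicted sequences made up 7 of the 12 largest rises. novel713_mature and novel139_mature had 0 counts in control libraries and 806 ± 352 and 132 ± 83.1 CPM in xanthatin libraries, at least 64.7-fold and at least 10.6-fold higher. novel287_mature and novel373_mature rose by ratios of 46.1 (exact 95% Poisson interval 15.6 to 225) and 41.9 (7.37 to 1670), on 3 counts and 1 count in control libraries. novel643_star, novel438_mature and novel643_mature rose by log2 fold changes of 3.97, 3.47 and 2.82. novel550_mature, the most abundant sequence in xanthatin libraries, rose from 34166 ± 4891 to 175840 ± 13955 CPM (log2 fold change 2.36, SE 0.13). It alone took 15.6% ± 1.40 of xanthatin counts, of the 21.3% that predicted sequences held. Among called predicted sequences, 13 were higher and 12 lower, so the larger share does not mean that predicted sequences rose in general. Of the known miRNAs, miR-7-5p, enriched in neural and endocrine cells, rose from 360 ± 155 to 1914 ± 362 CPM, and miR-10401-5p rose by a ratio of 41.0 (11.2 to 340) on 36, 23 and 156 counts against 2 in control libraries. The calls of novel139_mature (adjusted p = 0.0532 to 0.0601) and miR-10401-5p (0.0558 to 0.0727) were lost without any one control replicate, that of novel373_mature without control replicate 1 or 3 (0.0654 and 0.0666), and that of novel643_star without control replicate 1 or 2 or any xanthatin replicate (0.0663 to 0.107). novel643_star, with 1, 2 and 29 control counts, was at 6.90 without control replicate 3, and novel373_mature was at least 10.2-fold higher without control replicate 2, which held its control count. The fitted log2 fold change of novel287_mature was 5.49, and 6.30 without control replicate 1, which held 2 of its 3 control counts. Calls were also lost with no count filter or a filter of mean CPM 10 for novel139_mature (adjusted p = 0.0806 and 0.0915) and novel373_mature (0.0809 and 0.0933). That of novel643_star was lost with that CPM filter (adjusted p = 0.0808), totals only (0.0597) or the total implied by the TPM (0.0524). With limma-voom they were lost for novel139_mature (0.0555), novel438_mature (0.0762) and miR-10401-5p (0.25). That of miR-10401-5p was also lost with limma-trend at a pseudocount of 0.1 (adjusted p = 0.0647) and on TPM (0.0585).

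Of 10 tested miRNAs raised in hepatocellular carcinoma, 4 rose (5 adjusted over the list alone) and miR-10b-5p fell. The 4 were miR-224-5p (26092 ± 3079 to 47771 ± 3757 CPM, log2 fold change 0.87), miR-21-5p (1.36), miR-183-5p (1.07) and miR-182-5p (0.65), and the camera adjusted p was 0.194. The call of miR-182-5p was lost without any one library (adjusted p = 0.0554 to 0.153). It was also lost with RLE, upper-quartile factors, totals only (0.30), the total implied by the TPM, a filter of mean CPM 10, limma-trend on TPM, known names only, thinned libraries and without novel550_mature (adjusted p = 0.0517 to 0.342). Of 9 tested miRNAs lowered in hepatocellular carcinoma, miR-122-5p fell (1 adjusted over the list alone), and miR-99a-5p was at 9048 ± 830 and 9855 ± 509 CPM (camera adjusted p = 0.275). Of 5 tested p53-responsive miRNAs, miR-143-3p fell and miR-192-5p rose (2 and 1 adjusted over the list alone; camera adjusted p = 0.853). Of 5 tested miRNAs of hypoxia, redox and ER stress, miR-193b-5p fell and miR-146a-5p rose (1 and 1 adjusted over the list alone; camera adjusted p = 0.828), and miR-30d-5p was at 3961 ± 944 and 2829 ± 282 CPM. It did not pass, except with library totals only (-0.83, adjusted p = 0.0349).

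In the clusters of miR-17, miR-92 and miR-106b, 2 of 8 tested members fell, miR-92a-3p (79168 ± 6728 to 50803 ± 3792 CPM, log2 fold change -0.64) and miR-92a-1-5p (-2.42), and miR-106b-3p rose (0.63); adjusted over the list alone, 3 fell and 2 rose, and the camera adjusted p was 0.853. The call of miR-106b-3p was lost without any one control replicate or xanthatin replicate 1 or 2 (adjusted p = 0.0518 to 0.0658) and with totals only (0.28, adjusted p = 0.174). miR-92a-3p lost its call without control replicate 2 (-0.55, adjusted p = 0.0524), with upper-quartile factors (-0.56, adjusted p = 0.0523) and with no count filter (-0.37, adjusted p = 0.118). miR-25-3p, at 0.52 (adjusted p = 0.0513), passed without control replicate 3 (0.70, adjusted p = 0.0148) and also with RLE, upper-quartile factors, totals without the 10 most abundant, no filter, DESeq2, limma-voom, limma-trend at 3 pseudocounts, thinned libraries and without novel550_mature (0.50 to 0.79, adjusted p = 9.94e-04 to 0.0485). In the group of miR-10, miR-99, miR-100 and miR-125, miR-100-5p rose (31107 ± 3832 to 45133 ± 221 CPM, log2 fold change 0.54; 0.19, adjusted p = 0.192, with library totals only) and miR-10a-5p (-0.57), miR-10b-5p and miR-99b-3p (-2.81) fell, 4 of 9 tested (3 up and 3 down adjusted over the list alone; camera adjusted p = 0.853). The call of miR-10a-5p was lost without control replicate 2 or 3 or xanthatin replicate 1 or 3 (adjusted p = 0.0516 to 0.170). It was also lost with RLE, upper-quartile factors, totals without the 10 most abundant, no filter (-0.30), a filter of mean CPM 10, DESeq2, known names only and without novel550_mature (adjusted p = 0.0658 to 0.391). The call of miR-99b-3p was lost without control replicate 1 or 2 or any xanthatin replicate (adjusted p = 0.0625 to 0.13), and with upper-quartile factors, no filter, a filter of mean CPM 10 and thinned libraries (0.0556 to 0.118). The list of the miR-200 family, which maintains epithelial identity, also held miR-205. Of its 5 tested members, miR-200c-3p fell (-1.25, SE 0.24), 1 fell adjusted over the list alone, and the camera adjusted p was 0.569. The call of miR-200c-3p was lost without control replicate 2 (-1.08, adjusted p = 0.0564) or with no count filter (-0.99, adjusted p = 0.121). miR-200b-3p was at -1.19 (adjusted p = 0.101) and miR-205-5p at -1.47 (adjusted p = 0.0994). Raw counts of miR-200c-3p were similar in the groups, at 191, 222 and 185 against 210, 210 and 229.

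miR-320c, chosen after its values were seen, passed the test among 4 tested members of the miR-320 family (3.90, SE 1.17; 0 adjusted over the list alone; camera adjusted p = 0.853), while miR-320a-3p and miR-320b were at -0.38 and -0.48. It was the 1 call of 77 whose groups overlapped in CPM, with raw counts of 12, 20 and 6 in control and 415, 1186 and 33 in xanthatin libraries. Its call was lost without any one control replicate (4.56 without replicate 2) or xanthatin replicate 1 or 2 (2.77 without replicate 2; adjusted p = 0.0914 to 0.136), and it was at 4.50 without xanthatin replicate 3 (adjusted p = 0.00864). It was also lost with upper-quartile factors, totals only, the total implied by the TPM, a filter of mean CPM 10, the robust fit, limma-voom and each limma-trend fit (adjusted p = 0.0516 to 0.362). None of the 3 tested chromosome 19 cluster members passed (camera adjusted p = 0.569), with miR-522-3p at -1.06 and miR-1323 at -1.58. None of 7 tested members of the miR-23, miR-24 and miR-27 clusters (adjusted p = 0.853; miR-27b-3p 0.42, miR-24-3p -0.10), 3 of the miR-181 family (0.853; miR-181b-5p 0.18, miR-181a-5p -0.51) or 4 of the miR-30 family (0.983; miR-30c-5p 0.22) passed. The miR-30 list had a median of -0.13, a mean of 0.24 and an upward test direction. The miR-15/16 and miR-29 families had 2 and 1 tested members, too few for a set test, and miR-16-2-3p, miR-424-3p and miR-29a-3p did not pass at -0.65, -1.21 and -0.71. miR-663a was at 0.17 (SE 1.79), with all its control counts in replicate 2, and without that library it was at least 17.6-fold higher (adjusted p = 0.0219). miR-29b-3p had too few counts for the test.

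Of the 10 most abundant miRNAs, miR-151a-3p and miR-423-5p did not pass, at 127701 ± 9436 and 137242 ± 7437 CPM (log2 fold change 0.10) and at 40300 ± 4841 and 35616 ± 1333 CPM (-0.18). With library totals as the only scaling both were lower (-0.24, adjusted p = 0.0296, and -0.52, adjusted p = 0.00463). miR-151a-3p was instead higher with RLE (0.20, adjusted p = 0.0439), totals without the 10 most abundant (0.25, 0.0158), no filter (0.38, 0.0117), DESeq2 (0.27, 0.00820) and without novel550_mature (0.23, 0.0482). Its direction thus depended on the processing. miR-423-5p was at 0.11 with no filter (adjusted p = 0.575). The 10 most abundant miRNAs of each library held 58.7% ± 1.24 of control counts and 66.4% ± 1.28 of xanthatin counts, and predicted miRNAs held 9.52% ± 1.46 and 21.3% ± 0.97. At least 1 count was seen for 463 ± 22.7 miRNAs in control and 601 ± 21.2 in xanthatin libraries, and at least 10 counts for 229 ± 22.7 and 330 ± 13.0. With libraries thinned to 63965 counts, an alternative added after the data were seen, these numbers were 452 and 458, and 221 and 175, so the second reversed. Each of these differences, before thinning, had an exact two-sided permutation p of 0.1, the smallest possible with 3 against 3, and 0.125 adjusted over 30 measures. Within the share of predicted miRNAs, novel550_mature alone took 15.6% ± 1.40 of xanthatin counts.

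miRNA counts made up 0.683% ± 0.024 of the total implied by the deposited TPM in control and 0.809% ± 0.042 in xanthatin libraries, but what the authors counted in that total is not stated. Of the called miRNAs, 76 of 77 had groups that did not overlap in CPM, as did 54.7% of all tested (chance 10%). Depth differed with treatment in every library, and with library totals as the only scaling the median log2 fold change of tested miRNAs was -0.49 instead of -0.16, with 22 higher and 60 lower calls (26.8% higher, against 44.2%). The balance went the other way with totals without the 10 most abundant (45 higher, 40 lower), without novel550_mature (42 and 40), with DESeq2 (51 and 49) and with no filter (37 and 30). The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. They also do not say whether the groups were prepared or sequenced together, so a batch that went with group, as depth did, cannot be told apart from treatment in any comparison above.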

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

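Of 1914 alternative values for 81 named miRNAs, 1676 kept direction and side of the threshold, 181 kept direction and lost the call, 33 gained a call and 24 changed direction, 1 of them with a call. Except where an alternative's construction shows it, the cause was not tested. Thinned libraries, the total implied by the TPM and the removal of novel550_mature were chosen after the data were seen. The 77 calls, 21 higher and 31 lower of them known names, became 49 (22 higher, 27 lower; 47 shared) with known names only, in part since predicted sequences were then not tested. Higher calls, 34 of them, became 22 with library totals only and 22 to 30 with a library left out. Replicate numbers did not pair the samples (correlations of deviations 0.12, -0.01 and -0.05 for numbers 1, 2 and 3, and not every sample correlated best with its own number). With a replicate block the calls became 54 (21 higher), list calls 2, miR-181a-5p 0.32 and the miR-30 list adjusted p = 0.944. The 4 list calls became 1 with limma-voom, 2 with limma-trend at each of 3 pseudocounts and on TPM, 2 with thinned libraries, 0 with an estimated correlation, 10 with fry, which does not compare a list with other miRNAs, and 2 to 4 with a library left out. The xanthatin excess of miRNAs with at least 10 counts became -46 after thinning, where miRNA totals are equal.

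Direction changed under totals only for miR-151a-3p (-0.24, adjusted p = 0.0296; called higher under 5 other alternatives), miR-99a-5p (-0.22), miR-30c-5p (-0.13), miR-181b-5p (-0.15), miR-663a (-0.18) and the miR-30 list (adjusted p = 0.934). Without a filter it changed for miR-423-5p (0.11), miR-24-3p (0.20) and the miR-181 and RNA fragment lists (both adjusted p = 0.771), and with the mean CPM filter for those 2 lists (both adjusted p = 0.933). DESeq2 changed it for miR-24-3p (0.067) and for the list of miR-10, miR-99, miR-100 and miR-125 and the miR-181 list (both adjusted p = 0.980). miR-24-3p also changed direction with totals without the 10 most abundant (0.054), known names only (0.017) and without novel550_mature (0.027), and miR-663a with thinned libraries (-0.088). miR-181a-5p was at 0.61 with limma-voom, 0.83, 0.84 and 0.71 with limma-trend at pseudocounts 1, 0.1 and 10, and 0.11 on TPM. The miR-30 list changed with limma-voom (adjusted p = 0.908), and it had adjusted p = 0.910, 0.898 and 0.943 with limma-trend at those pseudocounts, as did the RNA fragment list, 0.951 on TPM and 0.787 with fry. With a library left out, the ranges were -0.30 to 0.27 for miR-24-3p, -0.95 to 0.75 for miR-181a-5p, -0.50 to 8.62 for miR-663a (the latter fitted against 0 counts, at least 17.6-fold), and adjusted p = 0.804 to 0.930 for the miR-23, miR-24 and miR-27, 0.855 to 0.948 for the miR-30 and 0.721 to 0.937 for the RNA fragment list. Depth limits the control libraries most, since 3 counts there equal 34.7 to 39.9 CPM.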

Other observations

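Tests written only after their results were seen are those of serum RNA, shared let-7 reads, equal raw counts, the GGAG motif and hairpin arms. Chosen after their values were seen, miR-372-3p, miR-371b-3p and miR-371a-5p passed the test at log2 fold changes of -1.48, -1.44 and -1.48, on raw counts that were similar in the groups: 2048, 2295 and 2397 in control against 2148, 1936 and 2198 in xanthatin libraries, 1210, 1274 and 1343 against 1217, 1160 and 1280, and 910, 993 and 1049 against 914, 881 and 947. Among other known miRNAs, chosen in the same way, miR-148b-3p (1.46), miR-197-3p (1.90), miR-1-3p (-1.93), miR-1247-3p (-1.50), miR-1293 (-1.60) and miR-6754-3p (-1.90) passed the test, but each lost its call in at least 5 of the 6 fits without a library (adjusted p = 0.0525 to 0.142). miR-197-3p, with 14, 22 and 50 control counts, was at 2.67 without control replicate 3 (adjusted p = 0.0137), and miR-6754-3p, with 46, 78 and 143, at -1.30 without that library.

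Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls as the real one, which is the real split itself with 77 calls, and the highest of the other splits gave 0; with 10 splits a share under 0.05 cannot be reached.

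Among hepatocyte, 14q32, blood and stromal markers, 10 called miRNAs were lower in xanthatin libraries. In 20 thinnings to equal miRNA totals, 9 of the 10 kept their call in every one, while miR-493-5p was tested in 0 of them. Its median of 49 control counts and 0 xanthatin counts did not pass the count filter. Unequal miRNA totals alone thus did not make the 9 calls. Thinning keeps expected proportions, so it does not test other effects that go with depth. The median log2 fold change of the 10 was between -4.77 and -5.21 under 5 scalings. These members were chosen as called lower, and the scalings moved the median of all tested miRNAs only from -0.05 to -0.49. The outcome was thus nearly fixed in advance, and it shows only that none of these scalings removes the falls. Over all tested members, the medians were -1.35 for the hepatocyte, -7.68 for the 14q32, -1.25 for the blood and -1.84 for the stromal list. Serum or blood RNA in the control medium stays open. The pooled CPM of 5 rows restricted to blood cells and vessels in xanthatin libraries was 0.253 of the control mean (57, 71 and 117 against 231, 240 and 492). The highest xanthatin library was just above the bound of 0.5 of the lowest control. Raw pooled counts overlapped between the groups, at 20, 19 and 37 in control and 12, 17 and 21 in xanthatin libraries. miR-126-3p gave most of these counts (19, 16 and 22 against 11, 8 and 20). It is among the miRNAs with nearly equal raw counts below, whose falls may reflect depth if a fixed input exists. By the labels both groups had the same serum, and an effect of xanthatin itself or a batch that went with group, which may also lower these miRNAs, stays open and untested.

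In the let-7 family, 8 called members were higher in xanthatin libraries. After thinning, a median of 8 kept the call over 20 draws (range 7 to 8), so unequal miRNA totals alone did not make these calls. The members were chosen as called and thinning keeps their expected proportions. It therefore does not test other effects that go with depth. The median log2 fold change of the list was 1.67 to 2.11 under 5 scalings, so none of these removes the rise. The scalings moved the median of all tested miRNAs only from -0.05 to -0.49, too little to have done so. Sharing of reads with let-7a, let-7b, let-7c and let-7f was examined through the 5p arms of let-7i, let-7g, let-7d, let-7e and miR-98. Their median log2 fold change was 1.90, and 4 of them were called. Members of the family differ by few bases, so shared reads could raise these members too, and the test cannot decide. An effect of xanthatin on let-7 in vesicles stays a hypothesis, found and tested on the same libraries, and a batch that went with group stays open.

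Control libraries resembled each other less (mean Pearson correlation of log2 CPM across miRNAs 0.781) than xanthatin libraries did (0.914), though miRNAs are not independent replicates. After thinning to equal miRNA totals the difference was 0.102 (0.0961 to 0.109 over 20 draws), against unequal totals as the whole cause. No biological explanation was tested.

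Some miRNAs had nearly equal raw counts in all libraries although the totals differed between the groups. Counts were taken to fit where a chi-square test with 5 degrees of freedom gave p above 0.05. Of 244 tested miRNAs with at least 60 counts in all, 12 had 6 counts that fit a single Poisson mean, among them miR-371a-3p (201, 255 and 253 against 224, 224 and 251; a call lost without control replicate 2, adjusted p = 0.0522, and with no count filter, 0.0555) and miR-200c-3p (191, 222 and 185 against 210, 210 and 229), and 3 had counts that fit the miRNA totals. Xanthatin-to-control ratios under 0.8 or over its inverse gave at most 9, so the lead of 3 is within its counting error of 4.58 and a fixed amount of the same RNA or reads in every library cannot be told apart from a fall that happens to offset depth. That counting error was required only after the 12 and 9 were seen. If such an input exists, the falls of these miRNAs may reflect depth. The same holds for miR-372-3p, miR-371b-3p, miR-371a-5p and the hepatocyte markers miR-148a-3p and miR-483-5p, whose raw counts were also similar in the groups, and thinning to equal miRNA totals does not test it.

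GGAG, a motif bound by RNA-binding proteins that sort miRNAs into vesicles, was searched in the side of the hairpin that holds each miRNA, for 154 of 178 tested known miRNAs (86.5%). The mature sequences were not examined, so GGAG may lie in that side of the hairpin but outside the miRNA itself. The 36 with GGAG had a mean log2 fold change of -1.23 against -0.29 for the others, a difference of -0.94 (medians -1.02 and -0.07). The two-sided permutation p over 100000 draws was 0.0154, across miRNAs, which are not independent. The means use fitted values, not bounds, for miR-6892-5p and miR-432-5p (with GGAG) and miR-493-5p (without), which had 0 xanthatin counts. By the edgeR test, 8 of the 36 fell and 0 rose, among 27 that fell and 19 that rose. Adjusted for the G share of the arm, the difference was -0.76 (SE 0.40), and in tertiles of the G share it was 0.96, -1.05 and -1.56, so a role of G content cannot be told apart from the motif. A loss from these vesicles of miRNAs with GGAG in their side of the hairpin may be worth testing on new samples, with the mature sequences. Hairpin arms gave no such lead: the minor arm had the lower log2 fold change in 12 of 21 hairpins with both arms tested (exact sign test p = 0.664).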
